A study of Mus musculus with 10 samples.

How the data were processed

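The series holds ChIP-seq libraries from 2 mouse keratinocyte lines, MK1 and MK2: 2 of p63, 6 of histone marks and 2 of input chromatin. Per the labels' protocols, chromatin was sheared with a Bioruptor, p63 was precipitated with an antibody to p63, libraries were made with ThruPLEX kits, and 50 bp single-end reads were taken on a HiSeq 2500. The submitters' processing notes name Bowtie 1.1.1, SAMtools 1.1 and the build mm10. The peak caller, its threshold and the IDR threshold are not given in the sources used here.

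The file analysed is the authors' deposited list of p63 peaks. Per the labels, it was made by running IDR (irreproducible discovery rate, which keeps peaks ranked alike in both replicates) on the MK1 and MK2 p63 libraries. The deposited list has 3 columns, namely chromosome, start and end, and no score, summit, count or p-value. Peaks found in 1 line alone are not meant to pass that step, and MK1 and MK2 cannot be compared. Read depth is unknown, so a peak missing near a gene can mean no binding or too few reads. Fragment ends of single-end libraries are inferred, which limits how exactly a peak edge marks a binding site. Starts were converted from 0-based to 1-based positions.

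Genes came from a RefSeq table of the mouse assembly GRCm38.p6, which has the same chromosome coordinates as mm10. The match was checked on the data: 4.64% of peak midpoints lay within 500 bp of a protein-coding gene boundary, against 2.71% and 2.63% after shifting all peaks by 5 kb down or up and 2.15% and 2.18% after shifting them by 1000 kb. Of 49943 gene rows on the chromosomes, 340 with positions of unplaced or alternate scaffolds were left out, recognised by an end below 3 Mb on a chromosome other than Y. That left 49603 genes, 21779 of them protein-coding. The table gives gene extents but no strand, exons or sequence, and no genome was used here. Planned measures relative to transcription start sites were therefore taken relative to gene boundaries, meaning either end. Planned classes of promoter, untranslated region and exon were replaced by the 4 classes reported, and a chromosome's length by the span from its first to its last annotated gene. Planned work on p63 motifs, other motifs, short words and base composition was not run.

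Peak positions were compared with 1000 random placements of each peak on its own chromosome, giving two-sided empirical p-values no smaller than 0.0020. Placements outside assembly gaps were planned, but positions were drawn uniformly over the annotated span. They can fall in gaps or repeats where no peak can be called, which can enlarge the folds for gene proximity and clustering. Classes were adjusted together by Benjamini-Hochberg. For each of 20 gene lists, the number of genes with a peak midpoint within 25 kb of a boundary was compared with 100000 random lists of protein-coding genes. This is a permutation test of gene labels. Random lists were matched on 5 classes of gene length and 3 classes of gene density within 100 kb, and their smallest p is 2.0e-05. Benjamini-Hochberg adjustment was over the 20 lists. Of 326 list entries, 325 matched the gene table; Krt85 did not. A total of 9 genes stand in more than 1 list. Matched genes need not be neighbours, so lists of clustered genes that share peaks get too small a p. Circular shifts of all peaks, which keep that structure, were an alternative. They compare list genes with random positions, not with other genes, so general proximity of peaks to genes enters their folds. Peaks per chromosome were tested with two-sided exact binomial tests. Proximity to a gene does not show that the gene is regulated by the peak.

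The gene lists, the main tests and the rule for naming genes were fixed before the data were examined, apart from the replacements above. The Fisher test against control lists, the tests of families, peak width and X gene content, and the alternatives named as such in the closing section were chosen later. The rule named 12 fixed genes (Trp63, Krt5, Krt14, Perp, Cdkn1a, Fgfr2, Jag1, Ripk4, Dst, Itgb4 and Zfp750, and 1 that is not reported here), the 15 protein-coding genes with most peaks in the body or within 50 kb, and up to 4 genes of each list with most peaks within 25 kb. Ties in the count of 15 were broken alphabetically, because sites in the sequence could not be counted. Genes of the densest windows, microRNA genes and gene families were named after their values were seen, as was Krt42.

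The tests were checked on simulated data. With peaks placed at random, the placement test called 2.5% of 40 simulations, and with 5% of peaks moved to a gene boundary it called 100% and recovered an excess of 4.85 percentage points. Each simulated list was tested singly and called at an unadjusted p under 0.05. The list test called 3.0% of 400 random lists of 17 genes. It called 44.0% of lists with 50% of their genes near a peak and 95.0% of lists with 75%. These rates are not those of the adjusted calls reported here. The simulated lists were of scattered genes, so they do not cover clustered genes that share peaks. Even without adjustment, a list of this size with a moderate excess can miss the threshold.

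Alternatives covered the window around boundaries, the gene set, the placement of a peak by overlap in place of its midpoint, the null model, the distance for lists, nearest genes only, and the expectation per chromosome. A peak's nearest gene was the protein-coding gene with the nearest boundary, even where the peak lay inside another gene. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.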

Results

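The series measured where the transcription factor p63 sat on the genome of mouse keratinocytes. p63 is a member of the p53 family and a master regulator of stratified epithelia such as the epidermis. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in 2 similar mouse keratinocyte lines, MK1 and MK2. There were 10 libraries in 5 groups of 2, with 1 library per line in each group. The groups were p63 ChIP, ChIP for the histone marks H3K4me1, H3K4me3 and H3K27ac, and input chromatin. H3K4me1 marks enhancers, H3K4me3 marks active promoters and H3K27ac marks active elements of both kinds. The values below come from 1 list of p63 peaks made from both p63 libraries together. That list gives positions only, with no peak height, so its read depth is unknown and no spread between MK1 and MK2 can be given. Intervals in brackets are 95% Wilson intervals and cover counting error only. The histone and input libraries were not analysed here.

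The study's title concerns how the p63 regulatory landscape differs between mouse and human epidermis. The comparisons below address the mouse side of it: how many sites p63 occupied, which genes they lay next to, and how they were spread. Human sites were not analysed here. Positions are 1-based on mm10, and genes are given by symbol from the RefSeq annotation of the same assembly.

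The list held 8451 p63 peaks on all 21 chromosomes. They covered 2.84 Mb, or 0.107% of the annotated 2660 Mb of those chromosomes. The median width was 305 bp, with quartiles of 242 and 392 bp and a range of 138 to 1494 bp. No peaks touched or overlapped. The widest peak lay on chromosome 4 at 150870738 to 150872231.

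One comparison asked where p63 lay relative to protein-coding genes. Most p63 peaks lay inside genes or in the DNA between them, and few lay at a gene's edge. Of the 8451 peaks, 4141 (49.0%, interval 47.9 to 50.1) had their midpoint inside a gene and over 1 kb from either end. Another 658 peaks (7.79%, interval 7.23 to 8.38) were within 1 kb of a gene boundary, meaning either end of the annotated gene. Between genes, 1819 peaks (21.5%) were 1 to 25 kb from the nearest boundary and 1833 (21.7%) were farther away than 25 kb. Random positions on the same chromosomes, which were not kept out of assembly gaps, gave other shares. They were within 1 kb of a boundary in 3.18% of cases, so peaks were there 2.45 times as often. Peaks were inside genes 1.25 times as often as random positions (39.3%) and between genes at 1 to 25 kb 1.33 times as often (16.1%). They were over 25 kb from any gene only 0.525 times as often (41.3%). With all annotated genes in place of protein-coding ones, the class at 1 to 25 kb did not differ from random positions (25.1% against 24.9%, 1.01-fold, permutation p = 0.61). With protein-coding genes, each of these 4 differences had an adjusted permutation p of 0.0020, the smallest that 1000 random placements can give (two-sided, Benjamini-Hochberg). The annotation used here has no strand or exons, so a gene's start could not be told from its end, nor an exon from an intron.

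The distance of peaks to genes showed the same attraction at every scale tested. The median distance to the nearest protein-coding boundary was 17412 bp for peaks and 46535 bp for random positions. Within 5 kb of a boundary were 24.5% of peaks and 13.1% of random positions. Within 25 kb were 58.7% and 37.8%, and within 100 kb 86.9% and 64.9%. Each difference had permutation p = 0.0020, again the smallest possible. In all, 5965 of 21779 protein-coding genes (27.4%) had a peak within 25 kb of a boundary.

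**Figure D1:**
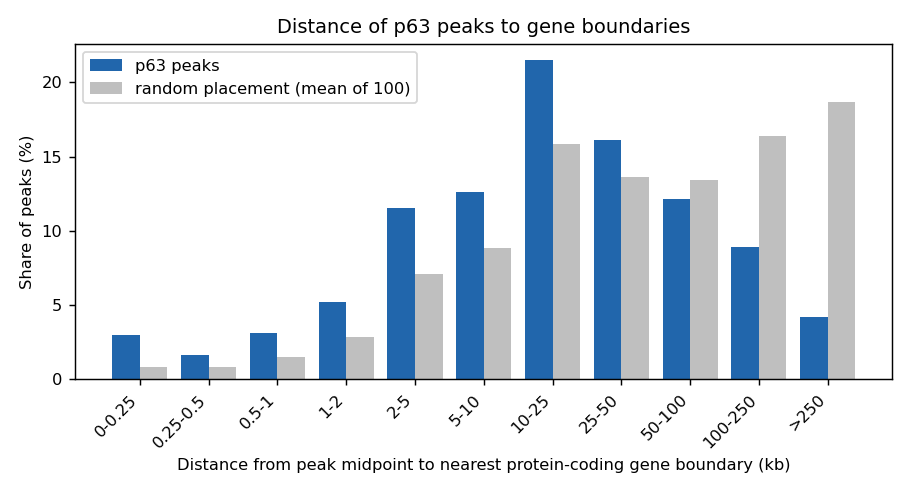
Share of peaks (%, vertical axis) in each class of distance from the peak midpoint to the nearest protein-coding gene boundary (kb, horizontal axis; the classes are of unequal width). Blue bars are the 8451 p63 peaks and grey bars are random positions on the same chromosomes (mean of 100 placements). Peaks exceed random positions in every class up to 50 kb and fall below them beyond 50 kb.

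A further comparison asked which genes p63 lay next to. The genes of basal keratinocytes were near p63 peaks more often than matched genes were, and none of the control lists of other cell types passed the test. A total of 20 gene lists was tested. Of these, 13 covered keratinocyte programmes, general regulators and keratins of other epithelial cells, and 7 covered other cell types as controls. A list gene counted if a peak lay within 25 kb of either of its boundaries, and the expectation came from 100000 random lists matched on gene length and local gene density. Random lists were not matched on expression, and their pool included families with few peaks, such as olfactory receptor genes (27 of 1109). Whether the excess goes beyond that of other genes active in keratinocytes was not tested. Of the 20 lists, 10 were above expectation at an adjusted p under 0.05 and 0 were below. In all, 147 of 225 genes in the 13 lists (65.3%, interval 58.9 to 71.2) and 15 of 91 in control lists (16.5%, interval 10.3 to 25.4) had a peak. That 3.96-fold difference had p = 8.0e-16 in a two-sided Fisher's exact test chosen after the data were seen. Of all protein-coding genes, 27.4% had a peak, so the control lists themselves lay below the general share. The 3.96 is therefore not an excess over all genes. The Fisher test was not matched on gene length and takes genes that share peaks as independent. The difference between the lists was 3.91-fold without the hair follicle and simple epithelial keratins and 2.31-fold within 100 kb. It was 8.02-fold when a peak within 25 kb counted only for its nearest gene. The nearest gene was the one with the nearest boundary, even where the peak lay inside another gene. For the 10 lists past the threshold, folds ranged from 0.91 to 4.33 within 10 kb and from 1.26 to 1.72 within 100 kb. They ranged from 3.21 to 4.91 with circular shifts of the peaks and from 2.26 to 5.63 with nearest genes within 25 kb. The folds with circular shifts are over random positions, not over other genes. Distances of a peak from a gene are those of its midpoint.

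Keratins of the basal layer and of wounded or proliferating epidermis were among the genes with peaks. Of 7 basal keratin genes, 6 had a peak within 25 kb where 1.93 were expected (3.11-fold, adjusted permutation p = 0.0082). Krt5, which encodes the type II keratin of basal cells, had 4 peaks. The nearest spanned 101713473 to 101714335 on chromosome 15, 0.999 kb beyond the gene's upper end. Next to it lay a 1166 bp peak at 101714459 to 101715624. Krt14, which encodes its type I partner, had 1 peak at 100208576 to 100208962 on chromosome 11, 1.259 kb from the gene. Krt6a had 4 peaks, the same 4 as Krt5, and was the nearest gene of 1 of them, at 0.202 kb. Krt15 had 1 peak at 0.822 kb. The peaks counted for Krt17 lay at least 23.12 kb away, and the nearest gene of the closest one was Krt42. The 6 genes shared peaks and fell into 4 separate loci. The count was no longer past the threshold within 10 kb (3.56-fold, adjusted permutation p = 0.063) or within 100 kb (1.66-fold, adjusted permutation p = 0.099).

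The adhesion machinery of the epidermis carried some of the densest groups of peaks: 4 of the 10 densest windows of 100 kb lay at Col17a1, Pkp1, Nectin1 and Dst. In the hemidesmosome and basement membrane list, which holds the genes that anchor basal cells to the dermis, 14 of 17 had a peak (5.76 expected, 2.43-fold, adjusted permutation p = 0.0004). Col17a1, which encodes a hemidesmosomal collagen, had 8 peaks within 25 kb. Itgb4, Itga3 and Lama5, which encode integrin subunits and a laminin chain, had 4 each. One of the Itgb4 peaks lay inside the gene, 0.27 kb from its lower end, at 115974871 to 115975120 on chromosome 11. Dst, which encodes the hemidesmosomal plakin BPAG1, had 0 peaks within 25 kb of a boundary and 9 inside its 400.8 kb body. This list's excess was not past the threshold within 100 kb (1.43-fold, adjusted permutation p = 0.071). In the desmosome and cell adhesion list, which covers cell-cell junctions, 15 of 18 genes had a peak (5.75 expected, 2.61-fold, adjusted permutation p = 0.0002). Pkp1, which encodes plakophilin 1, had 10 peaks, Nectin1 had 7 and Dsg3, which encodes a desmoglein, had 5. Perp, a desmosomal p53-family target, had 6 peaks. One at 18844792 to 18845165 on chromosome 10 spanned the lower end of the gene, with its midpoint 0.093 kb below it.

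**Figure D2:**
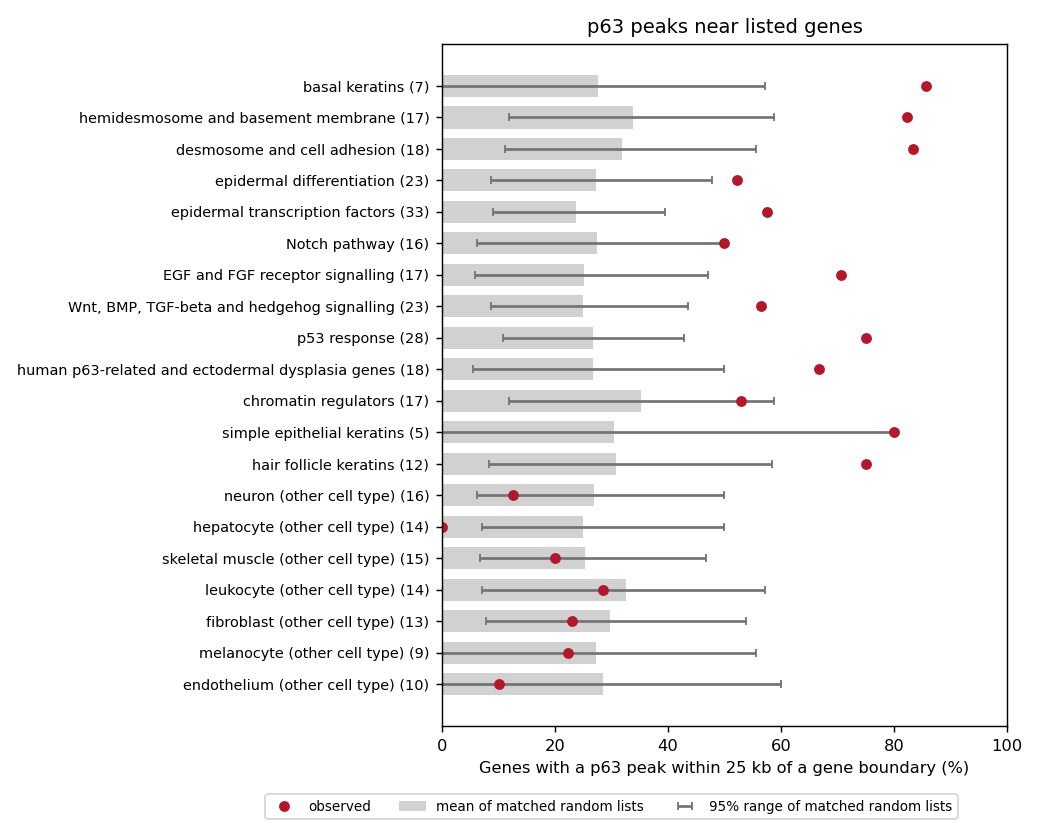
Share of the genes in each list with a p63 peak within 25 kb of a gene boundary (%, horizontal axis); the number of genes is in brackets after each list name on the vertical axis. Red points are the observed shares, grey bars the mean of 100000 matched random lists and lines the range that holds 95% of them. Desmosome genes reach 83.3%, while the 7 control lists stay at or below 28.6%.

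Genes of the p53 response were also near p63 peaks more often than expected. These are genes that p53 activates after DNA damage, and p63 recognises similar DNA. Of 28 such genes, 21 had a peak (7.49 expected, 2.81-fold), with an adjusted permutation p of 0.0002. Cdkn1a, which encodes the cell cycle inhibitor p21, had 4 peaks. One at 29090751 to 29091169 on chromosome 17 had its midpoint 0.019 kb from the lower end of the gene. Sfn, which encodes 14-3-3 sigma, had 6 peaks, Mdm2 had 3 and Zmat3 had 3.

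Transcription factors of the epidermis were near p63 peaks in 19 of 33 cases (7.80 expected, 2.44-fold, adjusted permutation p = 0.00027). Junb, which encodes an AP-1 subunit, had 6 peaks. Grhl3, which is needed for the skin barrier, had 3. Zfp750, which encodes a driver of terminal differentiation, had 3, among them a 650 bp peak at 121519615 to 121520264 on chromosome 11. Trp63, the gene of p63 itself, had 0 peaks within 25 kb of a boundary and 4 inside its 208.3 kb body. The widest of these spanned 736 bp at 25843549 to 25844284 on chromosome 16.

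Genes of terminal differentiation had a peak in 12 of 23 cases (6.28 expected, 1.91-fold, adjusted permutation p = 0.037). Ivl, which encodes involucrin, had 4 peaks and Abca12, which encodes a lipid transporter of the barrier, had 2. Sprr1a and Sprr1b, which encode cornified envelope proteins, had 2 each. The excess was not past the threshold when a peak within 25 kb counted only for its nearest gene (2.26-fold, adjusted permutation p = 0.10), when it did so at any distance (1.82-fold, adjusted permutation p = 0.25), or when gene bodies with 25 kb were used (1.81-fold, adjusted permutation p = 0.051).

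Among signalling genes, 12 of 17 in the EGF and FGF receptor list had a peak (4.28 expected, 2.80-fold, adjusted permutation p = 0.00096). Fgfr2, which encodes a receptor of epithelial growth signals, Met, Tgfa and Ereg had 3 each. In the list of Wnt, BMP, TGF-beta and hedgehog signalling, 13 of 23 had a peak (5.72 expected, 2.27-fold, adjusted permutation p = 0.0055). Wnt4 had 5, Wnt10a 4, and Tgfbr1 and Bmp7 3 each. Human genes of p63-related and ectodermal dysplasia syndromes had mouse counterparts near peaks in 12 of 18 cases (4.82 expected, 2.49-fold, adjusted permutation p = 0.0037), which was not past the threshold within 100 kb (1.26-fold, adjusted permutation p = 0.40). Ripk4 had 5 peaks, and Edaradd had 3, the nearest with its midpoint 0.030 kb from the gene's end.

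In the Notch pathway, which promotes keratinocyte differentiation, 8 of 16 genes had a peak (4.37 expected, 1.83-fold), and this did not pass the test (adjusted permutation p = 0.12). It passed within 100 kb (1.64-fold, adjusted permutation p = 0.018), with circular shifts of the peaks (2.65-fold, adjusted permutation p = 0.022) and with nearest genes, both within 25 kb (2.83-fold, adjusted permutation p = 0.012) and at any distance (2.29-fold, adjusted permutation p = 0.024). Jag2 and Hes1 had 3 peaks each and Jag1 had 2. Chromatin regulators had a peak in 9 of 17 cases (5.99 expected, adjusted permutation p = 0.29). Kdm6b had 3 peaks. Among keratins of simple epithelia 4 of 5 had a peak (1.52 expected, adjusted permutation p = 0.10), with 3 peaks at Krt8. Both of these lists passed with circular shifts, with adjusted permutation p of 0.024 for the chromatin regulators and 0.033 for the simple keratins. Circular shifts compare list genes with random positions, and peaks lay near genes in general. They therefore expect fewer genes with a peak: 3.40 against 5.99 for chromatin regulators and 3.02 against 4.37 for the Notch pathway. A pass under them does not show an excess over other genes.

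Keratins of the hair follicle, which are made by other cells of the skin, had a peak in 9 of 12 cases (3.70 expected, 2.43-fold, adjusted permutation p = 0.0082), but the ratio turned to 0.91 within 10 kb (adjusted permutation p = 1.0). Krt32 and Krt71 had 3 peaks each within 25 kb. The peak nearest to Krt71 was 16.482 kb away and had Krt5 as its nearest gene. Of the 12 genes, 3 were the nearest gene of a peak within 25 kb, where 1.30 were expected (2.31-fold, adjusted permutation p = 0.37).

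**Figure D3:**
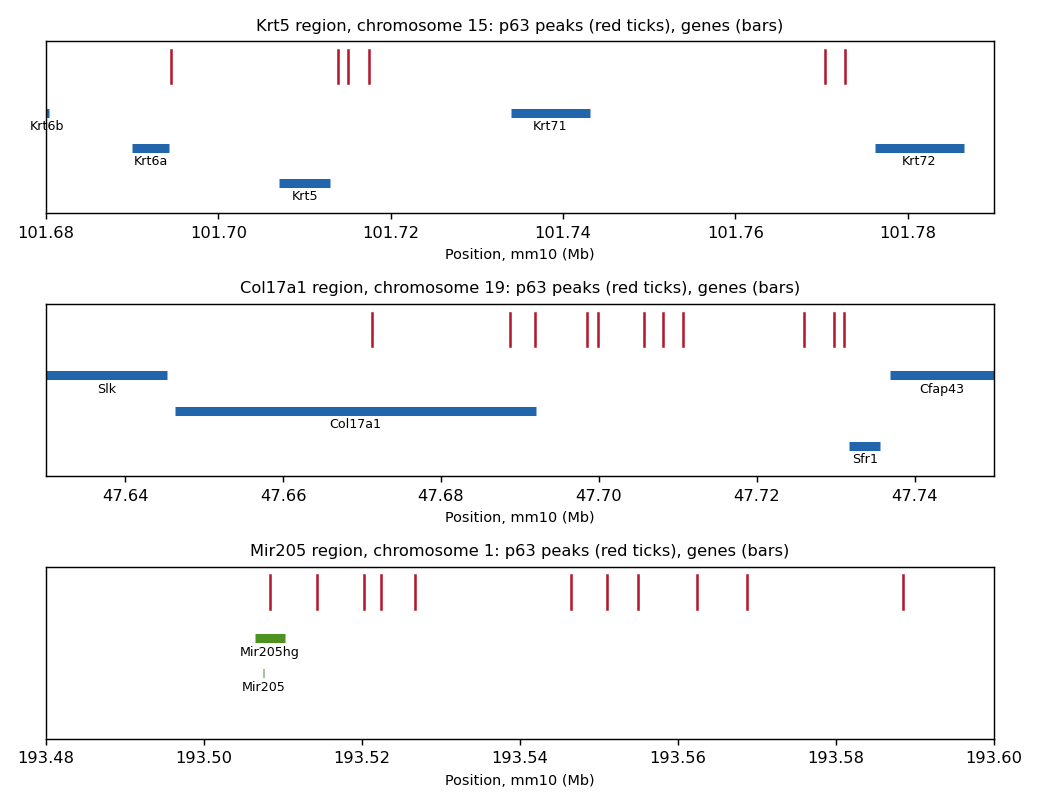
Maps of 3 regions on mm10 (horizontal axis, position in Mb), drawn to scale. Red ticks are p63 peak midpoints, blue bars are protein-coding genes and green bars are the Mir205 hairpin and its host transcript Mir205hg. The Krt5 map holds 6 peaks, the Col17a1 map 11 and the Mir205 map 11.

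Marker genes of other cell types were near peaks less often than expected in each of the 7 lists, with no difference past the threshold. The ratio turned above 1, without passing, for muscle, leukocyte, fibroblast and melanocyte genes under circular shifts, for leukocyte genes with unmatched genes and for neuronal genes with nearest genes at any distance. The neuronal list had 2 of 16 genes with a peak (4.29 expected, adjusted permutation p = 0.40), namely Rbfox3 and Grin1. The skeletal muscle list had 3 of 15 (3.81 expected, adjusted permutation p = 0.98), with Tnni2 at 2 peaks. The leukocyte list had 4 of 14 (4.56 expected, adjusted permutation p = 1.0), with Cd68 at 2. The fibroblast list had 3 of 13 (3.86 expected, adjusted permutation p = 0.98), which were Vim, Thy1 and Twist2. The melanocyte list had 2 of 9 (2.46 expected, adjusted permutation p = 1.0), which were Sox10 and Pmel. The endothelial list had 1 of 10 (2.84 expected, adjusted permutation p = 0.43), which was Pecam1. None of 14 hepatocyte genes had a peak, which allows a share of up to 21.4% (3.48 expected, adjusted permutation p = 0.062). With unmatched random genes as the null, the hepatocyte list was below expectation (adjusted permutation p = 0.042).

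It was then asked whether p63 bound in clusters. It did: 2459 peaks (29.1%, interval 28.1 to 30.1) had another peak within 10 kb, against 6.81% of random positions (4.28-fold, permutation p = 0.0020, the smallest possible). The median distance to the nearest other peak was 28410 bp, against 99943 bp at random. Joining peaks within 10 kb left 7060 sites. The densest 100 kb windows held 11 peaks, where random placements reached 5.3 on average. There were 2 such windows. One lay at 47671067 to 47731181 on chromosome 19, in and above Col17a1. The other, at 193508030 to 193588664 on chromosome 1, held no protein-coding gene and started inside Mir205hg, the host transcript of the epithelial microRNA Mir205. Windows of 10 peaks lay at Pkp1 and Tnnt2 on chromosome 1, at Sdc1 on chromosome 12 and at Sik1 on chromosome 17. Sdc1 encodes a cell surface proteoglycan and Sik1 a protein kinase.

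Counting peaks inside a gene or within 50 kb of it, the 15 genes with the most were named, with ties broken alphabetically. Cfap43 had 13, but 2 were in its body and its window covered part of the cluster at Col17a1, which had 11. Nectin1 also had 11. With 10 each came Amotl1, Btbd11, Casq2, Foxp1, Pkp1, Sfr1 and Tiam1, and with 9 each Ank3, Auts2, Bcar3, Dip2b and Dst. Other genes with 9 fell outside the 15 by the alphabetical rule. Sfr1 had 0 peaks in its body, and its window also covered part of the cluster at Col17a1. Casq2 had 2 peaks in its body and was the nearest gene of 3 peaks. Long genes have more room for peaks in this count. Foxp1 spans 597.4 kb and Auts2 1106 kb.

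A last comparison set the peaks of each chromosome against its annotated length. Chromosome 11, which carries the type I keratin cluster, had 646 peaks or 1.71 times the expected number (adjusted exact binomial p = 3.4e-37), although relative to its share of protein-coding genes it had 1.04 times the expected number (adjusted exact binomial p = 0.36). Chromosome 15, which carries the type II keratin cluster, had 415 peaks, 1.30 times the expected number by length (adjusted exact binomial p = 7.3e-07) and 1.38 times by genes. Keratin genes (Krt) of all chromosomes had 34 distinct peaks near them, few beside these counts. By genes, chromosomes 12 (1.62 times) and 18 (1.44 times) had higher ratios than chromosome 15. By length, chromosomes 12 and 18 were at 1.15 and 1.02 times. Chromosome 19 had 1.45 times the expected number by length and 0.983 times by genes. Chromosome 14 had 280, or 0.725 times (adjusted exact binomial p = 3.0e-08). The X chromosome had 155 peaks where 532 were expected, 0.291 times by length (adjusted exact binomial p = 1.9e-85) and 0.415 times by genes. The Y chromosome had 2. By length, 11 chromosomes were above and 8 below at an adjusted p under 0.05 in two-sided exact binomial tests, and 2 passed neither way. By gene share, 8 were above and 6 below, and without X and Y 5 were above and 6 below. These tests take peaks as independent, although peaks cluster. With peaks within 10 kb joined into sites, 8 were above and 6 below, and chromosomes 6, 12, 13, 16 and 17 no longer passed. Chromosomes 1, 2, 3, 7, 13, 17 and 19 changed sides of 1 when gene share replaced length, so their ratios give no firm direction.

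**Figure D4:**
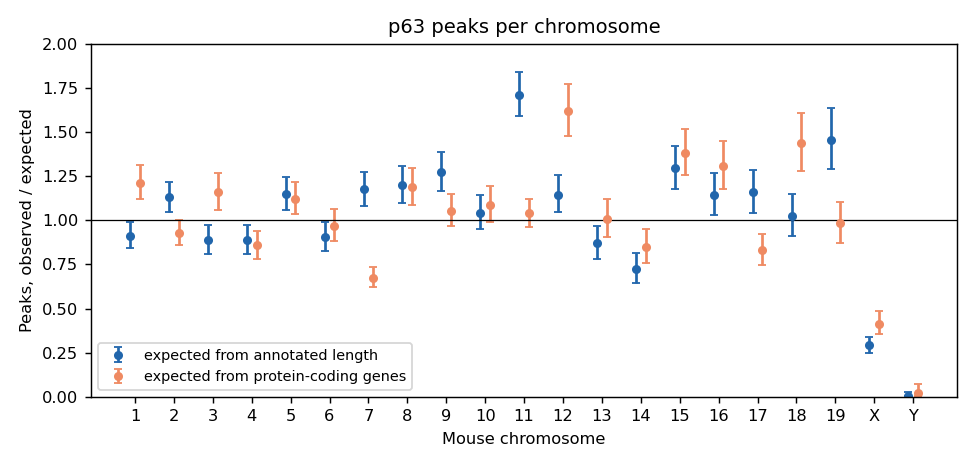
Observed over expected number of p63 peaks (vertical axis, ratio) on each mouse chromosome (horizontal axis). Blue points use the annotated length and orange points the number of protein-coding genes for the expectation, and lines are 95% Wilson intervals of the count. X (0.291 and 0.415) and Y lie below 1 in both, and chromosome 11 is at 1.71 by length and 1.04 by genes.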

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

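Circular shifts for positions, joining of peaks into sites, nearest genes within 25 kb, gene bodies with 25 kb, leaving out Y, and the comparison of the 13 other lists with the control lists, with all its settings, were chosen after seeing the data. The class between genes at 1 to 25 kb was not past the threshold with all annotated genes (1.01). Circular shifts keep the spacing of peaks, so they cannot test clustering and are not counted for it below. The number of peaks, the other classes of position, the distances to genes, the clustering and the ratio to control lists kept their direction and their side of the threshold in every alternative run for them. So did the desmosome, transcription factor, p53 response, EGF and FGF, and Wnt lists. The number of lists past the threshold stayed within 1.5 times of 10 throughout. Without X and Y, 11 chromosomes passed in place of 19. By gene share, the ratio changed sides for chromosome 1 (1.21), 2 (0.930), 3 (1.16), 7 (0.676), 13 (1.01), 17 (0.831) and 19 (0.983). Without X and Y it did so for 10 (0.961) and 18 (0.943). Both changes follow from the expectation used.

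Some lists lost their call. Within 100 kb these were basal keratins (1.66), hemidesmosome genes (1.43) and dysplasia genes (1.26). Within 10 kb it was basal keratins (3.56), while hair follicle keratins turned to 0.91. With nearest genes within 25 kb, differentiation (2.26) and hair follicle keratins (2.31) lost it. The planned nearest-gene setting has no distance limit, so it changes both choices: there differentiation (1.82) and hair follicle keratins (2.26) lost the call, and neuronal genes turned to 1.21 without passing. With gene bodies and 25 kb, differentiation (1.81, adjusted permutation p = 0.051) lost it. Other lists gained a call: the Notch pathway within 100 kb (1.64), with circular shifts (2.65) with nearest genes (2.29) and with nearest genes within 25 kb (2.83), and with circular shifts also chromatin regulators (2.65) and simple keratins (4.83). Under circular shifts, muscle (1.21), leukocyte (1.61), fibroblast (1.27) and melanocyte (1.26) genes moved above 1 without passing; that null compares list genes with random positions, not with other genes. With unmatched genes, leukocyte genes were at 1.04 and hepatocyte genes, at 0, passed. Where no reason is given, the cause was not tested. No paired analysis was possible because the single list combines MK1 and MK2. For that reason leaving out a line was not run. Stricter peak scores, GC-matched placements and all sequence alternatives were not run, since the list has no score and no genome was used. Unknown depth limits any statement about genes without a peak.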

Other observations

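The microRNA genes named, the tests of gene families and of widths near gene lists, the test of gene content on X and the count of nearest genes within 25 kb were chosen after the data were seen. Gene families, taken as symbols that share a stem, gave a wider view of where p63 lay. Of 273 families with at least 10 genes, keratin genes (Krt) had the clearest excess, with 38 of 53 near a peak (16.7 expected, 2.28-fold, adjusted permutation p = 0.0014). Solute carriers (Slc) were also above expectation, with 146 of 375 (1.26-fold, adjusted permutation p = 0.025), as were ankyrin-repeat genes (Ankrd), with 25 of 47 (1.85-fold, adjusted permutation p = 0.025). Hoxa genes had a peak in 9 of 11 cases (3.29-fold, adjusted permutation p = 0.0070), but these rested on 3 separate peaks, and all 12 Pcdhga genes shared 1 peak. Olfactory receptor genes (Olfr) were far below, with 27 of 1109 (0.132-fold, adjusted permutation p = 0.0014), and so were vomeronasal receptors (Vmn), with 9 of 352 (0.139-fold). None of 47 Pramel genes had a peak, where 10.3 were expected, and 1 of 33 Rhox genes had one (9.72 expected, 0.103-fold, adjusted permutation p = 0.0089). Zinc finger genes (Zfp) had 82 of 397 (0.685-fold, adjusted permutation p = 0.0044) and cytochrome P450 genes (Cyp) 14 of 99 (0.508-fold, adjusted permutation p = 0.038). Tandem members share peaks, so these p-values are too small.

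No test against expectation was run for the microRNA genes. Their distances run from a peak midpoint to the lower coordinate of the gene. Mir205 and its host Mir205hg had 5 peaks within 25 kb, the nearest 0.861 kb from that of Mir205. Mir203, which is linked to keratinocyte differentiation, had 1 at 4.597 kb. Mir34a had 1 at 19.332 kb, and Mir34b and Mir34c shared 1 at 2.376 and 2.904 kb. Mir21a had 2, the nearest at 16.003 kb, while Mir200c and Mir17 had 0. Peaks near the basal keratin, hemidesmosome, desmosome, transcription factor and p53 response lists were wider than others. The medians were 356 bp for 186 peaks and 304 bp for the rest (permutation p = 1.0e-05, the smallest possible). Of the 1691 widest peaks (420 bp or more), 35.0% (interval 32.8 to 37.3) had another peak within 10 kb, against 24.1% (interval 22.1 to 26.2) of the 1659 narrowest (229 bp or less).

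The X chromosome held 0.291 times the peaks its length predicts. A low number of genes for its length is argued against as the sole cause. Of 963 X genes, 122 had a peak, where matched autosomal genes gave 238 (95% range 214 to 263), a ratio of 0.512. Matching was on gene length and local gene density, so the kinds of gene on X were not tested. A single copy of X, which would lower ChIP coverage there, may contribute, but the X copy number of MK1 and MK2 is not given in the sources used here. It predicts narrower peaks, and X peaks had a median of 262 bp against 306 bp on autosomes, a difference of -44 bp (permutation p = 0.00014). Weaker binding on X would narrow peaks too, so it stays open, as does mapping of reads to repeats, which was not tested. No biological explanation was tested.

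Hair follicle keratins were near peaks although they are not genes of basal keratinocytes. They lie in the same clusters as Krt5 and Krt14, and peaks nearer to those neighbours are a candidate explanation. When a peak counted only for its nearest gene, 3 of 12 hair follicle keratins had one, inside the 95% range of 0 to 4 for matched lists (2.26-fold, adjusted permutation p = 0.40). That count had no distance limit; within 25 kb it was also 3 (2.31-fold, adjusted permutation p = 0.37). Both folds were close to the 2.43 of the full count, and with 12 genes the test has little power, and sites that act across the cluster stay open. No biological explanation was tested.

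Peaks gathered in clusters more than placements at randomly drawn genes did. If broad regions had been split into closely adjoining calls, most neighbours would lie within 1 kb. Of 1391 neighbouring pairs with midpoints within 10 kb, 14.3% (interval 12.6 to 16.2) had midpoints within 1 kb. This argues against splitting into calls that close. It cannot decide on regions of several kb, or on adjoining wide peaks, whose midpoints can lie over 1 kb apart. If peaks gathered only because genes do, placements at random genes with the same distances would match them. Those gave 19.2% with a neighbour within 10 kb, against 29.1% observed, a ratio of 1.52. The placements drew on all protein-coding genes alike, although 27.4% of them had a peak within 25 kb. Whether peaks cluster beyond the positions of the genes near p63 was therefore not tested. Open chromatin shared by several sites, or copies of p63 sites in tandem, were not tested, and no biological explanation was tested.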
